A study of Mus musculus with 3 samples.

How the data were processed

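Hearts of male C57/B6J mice were dissociated with collagenase and passed through a 70 µm strainer, and cells were captured with a 10x Genomics 3-prime kit of version 3, per the labels' protocols. There were 3 libraries, 1 each of WT, Myh6-R404Q and Prkag2-p.R299Q, sampled as total cells. Reads were aligned to the mouse assembly mm10 and counted with Cell Ranger 7.0.1, per the submitters' processing notes. The deposited values are UMI counts per gene and barcode for 32285 genes, with barcodes already called as cells. Whether intronic reads were counted, the aligner settings and the number of animals pooled per library are not given in the sources used here.

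The matrix deposited for Myh6-R404Q is an aggregate of libraries, as its barcode suffixes show. Its 7951 barcodes of suffix 1 equal the Prkag2-p.R299Q matrix and its 18033 barcodes of suffix 2 equal the WT matrix, with 0 entries that differ. Its 12662 barcodes of suffix 3 stand in no other matrix and were used as the Myh6-R404Q library. Using the matrix as deposited is an alternative that was chosen after the data had been seen.

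Barcodes needed at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs, which 18033, 12661 and 7951 barcodes passed. Doublets were called in each library with Scrublet in scanpy 1.11.5, at an expected rate of 0.8% per 1000 barcodes. They came to 3241 in WT (17.97%), 2194 in Myh6-R404Q (17.33%) and 1178 in Prkag2-p.R299Q (14.82%), where 14.4%, 10.1% and 6.36% were expected. The kept 14792, 10467 and 6773 cells had median mitochondrial shares of 2.71%, 2.12% and 1.82%. A class with 0 cells seen could still make up 0.0203%, 0.0287% and 0.0443% of the cells, taking 3 divided by the number of kept cells as the limit. Free RNA in the droplets was not removed, and empty droplets were not used here.

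Counts were scaled to 10000 per cell and log transformed. From 2000 variable genes, ranked by dispersion in 20 bins of mean expression within each library and averaged over libraries, 30 principal components were taken. Scaled values were limited to 10. A shared neighbour graph over 20 neighbours was clustered with leidenalg 0.10.2 at resolution 0.8, and no correction between libraries was applied. The 21 clusters were named from 22 marker lists: the class with the highest mean marker score was taken if the score was at least 0.5 log2 units and at least 3 markers were detected in 5% of the cells. A cluster with at least 2 cell cycle genes among its 10 leading genes was set aside as cycling. A further check, on leading genes that belong to another class, was loosened after a first clustering had been seen; every named cluster also passed the stricter form. This gave 13 named classes, and the 8 with at least 200 cells in each library were compared. T cell lists were not compared, because the T and NK cell-like class was smaller.

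UMIs were summed over the cells of a class in each library and expressed as CPM of the class total. Log2 ratios used a pseudocount of 1 CPM. Folds have exact conditional binomial intervals, shares exact binomial intervals, CPM exact Poisson intervals and share ratios log-normal intervals, all at 95%. With 1 library per genotype no test between genotypes was made and no genes were counted as changed. For 35 gene lists, the median log2 ratio was taken over members with at least 10 CPM in either library, if at least 3 were measured. Its interval comes from 1000 Poisson draws, and its percentile from 10000 random lists matched in 20 bins of expression. The percentile describes a position and is not a test, since the genes of a cell vary together. The comparisons were Myh6-R404Q with WT, Prkag2-p.R299Q with WT, and Prkag2-p.R299Q with Myh6-R404Q.

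Genes were named by a rule on size. In each class and comparison these were the 10 highest and the 10 lowest log2 ratios among genes with at least 50 CPM in either library, at least 2-fold, and an interval beyond 1.5-fold. Their CPM also had to reach at least 1/5 of that in the class where the gene was highest in the same library, as a guard against free RNA. Mitochondrial, ribosomal, hemoglobin, immunoglobulin, predicted genes, Xist, Tsix and genes of the Y chromosome were left out. Of each list, the 4 members with the highest mean CPM and any member past 2-fold could be named under the same guard, and a few genes were named in advance whatever their size. Myh6 and Prkag2 were given in every library. Coordinates are from a GENCODE annotation of mm10, in which all 214 genes looked up were found.

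The size rule was checked on simulated counts at the depth of the real classes, with 100 genes altered at each fold. The counts were Poisson draws from the WT profile of the class, with no variation between animals or libraries. The check therefore covers counting error only, and it did not test the guard against free RNA. In fibroblast-like cells of Myh6-R404Q, 50% of genes altered 2-fold and 99% of those altered 4-fold were found, and in cardiomyocyte-like cells of Myh6-R404Q 40% and 98%. In each of the 4 main classes and both mutants 0 unaltered genes were found. The intervals held the true value for 95.0% of genes in both of those classes.

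Correlation between the mutants' ratios was set against 100 mock draws. In each, 3 mock libraries with the real numbers of cells were drawn at random, with replacement, from the WT cells of the class. Their UMI totals were not matched to the real ones. Alternatives fixed in advance were a mitochondrial limit of 10%, a minimum of 1000 UMIs, no doublet removal, doublets removed at a fixed rate, resolutions of 0.4 and 1.6, and separate clustering of each library. Others were cells weighted equally, TMM scaling, cells thinned to 1000 UMIs, other CPM and fold limits, a pseudocount of 10 CPM, lists without members that are higher in another class, shares among fewer classes and all barcodes. Leaving out a cardiomyocyte-like cluster of low UMIs was chosen after the data had been seen, as was leaving out the cardiomyocyte-like cluster led by Nppa or the larger mesothelial-like cluster with Msln among its leading genes, both from resolution 1.6. Effects of alternatives are given for the results the text reports; that scope was set after a wider set of 404 list medians and 2406 gene ratios had been computed, in which 144 and 459 changed sign under some alternative, 23 and 66 of them with an interval that excluded 0. Thinning left out the 3965, 1482 and 788 cells with fewer UMIs. Work was done in Python 3.11.15 with anndata 0.12.19, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.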

Results

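Hearts of wild-type mice (WT) were compared with hearts of mice carrying either of a pair of point mutations linked to hypertrophic cardiomyopathy, a disease of thickened heart muscle. Myh6-R404Q alters the alpha myosin heavy chain, the main motor protein of adult mouse heart muscle. Prkag2-p.R299Q alters the gamma 2 subunit of AMP-activated protein kinase, a sensor of cellular energy that also bears on glycogen storage. Per the labels' protocols, single cells were released from the heart with collagenase. They were profiled by droplet sequencing of transcript 3-prime ends, with a unique molecular identifier (UMI) on each captured transcript. There was 1 library per genotype, so no difference below has a replicate check and no test between genotypes was made. Values are given with 95% intervals that cover counting error only.

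The WT library held 18033 barcodes and 41047991 UMIs, with a median of 1559 UMIs per barcode. The Prkag2-p.R299Q library held 7951 barcodes, 31385005 UMIs and a median of 2537. The matrix deposited for Myh6-R404Q held 38646 barcodes, of which 7951 were identical in every entry to the Prkag2-p.R299Q matrix and 18033 to the WT matrix. The remaining 12662 barcodes, with 38251499 UMIs and a median of 2043, were taken as the Myh6-R404Q library. That assignment rests on elimination, since no label in the matrix names the genotype of a barcode. After filters and removal of doublets, 14792 WT, 10467 Myh6-R404Q and 6773 Prkag2-p.R299Q cells were kept, with medians of 1414, 1849 and 2343 UMIs.

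The mutated genes themselves were counted first. Over all kept cells Myh6 (chromosome 14, 54941921 to 54966927, minus strand, mm10) was at 6473 CPM (counts scaled to the same total in each library or class) in WT, 6000 in Myh6-R404Q and 7057 in Prkag2-p.R299Q. Prkag2 (chromosome 5, 24862744 to 25100642, minus strand) was at 137, 120 and 127 CPM. A point mutation need not alter a 3-prime count, so these levels do not check the genotype labels. In cardiomyocyte-like cells Prkag2 was at 66.7 CPM (interval 61.5 to 72.1) in WT, 70.3 (64.4 to 76.7) in Myh6-R404Q and 69.4 (63.9 to 75.1) in Prkag2-p.R299Q, with no difference detectable at this depth.

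The comparison of cell classes asked whether the makeup of the heart differed by genotype. Class markers, gene lists and the size rule for naming genes were fixed before the data were examined. Clustering gave 21 clusters, and 13 classes were named from marker genes as fibroblast-like, endothelial-like, cardiomyocyte-like, macrophage-like and so on. Mesothelial-like cells, the lining of the heart's surface, were 12.96% of kept cells in Myh6-R404Q (12.33 to 13.62) and 8.43% in Prkag2-p.R299Q (7.78 to 9.12), against 5.37% in WT (5.01 to 5.74). These shares were 2.42 and 1.57 times that of WT. Fibroblast-like cells, the main source of collagen, were 27.5% in Myh6-R404Q, 32.8% in Prkag2-p.R299Q and 29.1% in WT, a ratio to WT of 0.945 (0.908 to 0.984) and 1.13 (1.08 to 1.18). Macrophage-like cells were 8.79%, 12.09% and 10.41%, a ratio of 0.844 (0.781 to 0.912) and 1.16 (1.07 to 1.26). Endothelial-like cells were 20.4%, 15.4% and 22.7%, and cardiomyocyte-like cells were 12.4%, 16.5% and 14.5%. Endocardial-like cells, the inner lining, were 6.36% in Myh6-R404Q against 3.50% in WT and 3.31% in Prkag2-p.R299Q. Lymphatic endothelial-like cells were 3.61% and 4.08% in the mutants against 5.80%. Pericyte-like cells were 4.09%, 4.72% and 4.77%.

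Among the rarer classes, smooth muscle-like cells were 0.535% in Myh6-R404Q and 0.281% in Prkag2-p.R299Q against 1.35% in WT, which is 0.396 (0.295 to 0.532) and 0.207 (0.130 to 0.332) times the WT share. Schwann-like cells, the glia of cardiac nerves, were 0.182% and 0.133% against 0.649%. B cell-like cells were 0.669% and 0.561% against 0.365%, and mixed myeloid-like cells, with markers of monocytes, neutrophils and dendritic cells, were 1.09% and 0.856% against 0.676%. T and NK cell-like cells were 0.812% and 0.605% against 0.784%. A share depends on how well each cell type survives digestion and passes the UMI minimum, and the libraries differed in depth. With at least 1000 UMIs per barcode the endothelial-like share in Myh6-R404Q (log2 ratio -0.15 to 0.0083) and the cardiomyocyte-like share in Prkag2-p.R299Q (0.19 to -0.043) moved to the other side of WT. With the Myh6-R404Q matrix taken as deposited, so did its fibroblast-like share (-0.081 to 0.013). The libraries also differed within classes: at a finer clustering 1 fibroblast-like cluster held 2074 WT, 973 Myh6-R404Q and 356 Prkag2-p.R299Q cells and another 595, 1026 and 948, so the class values below average over unlike mixtures of cells.

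**Figure D1:**
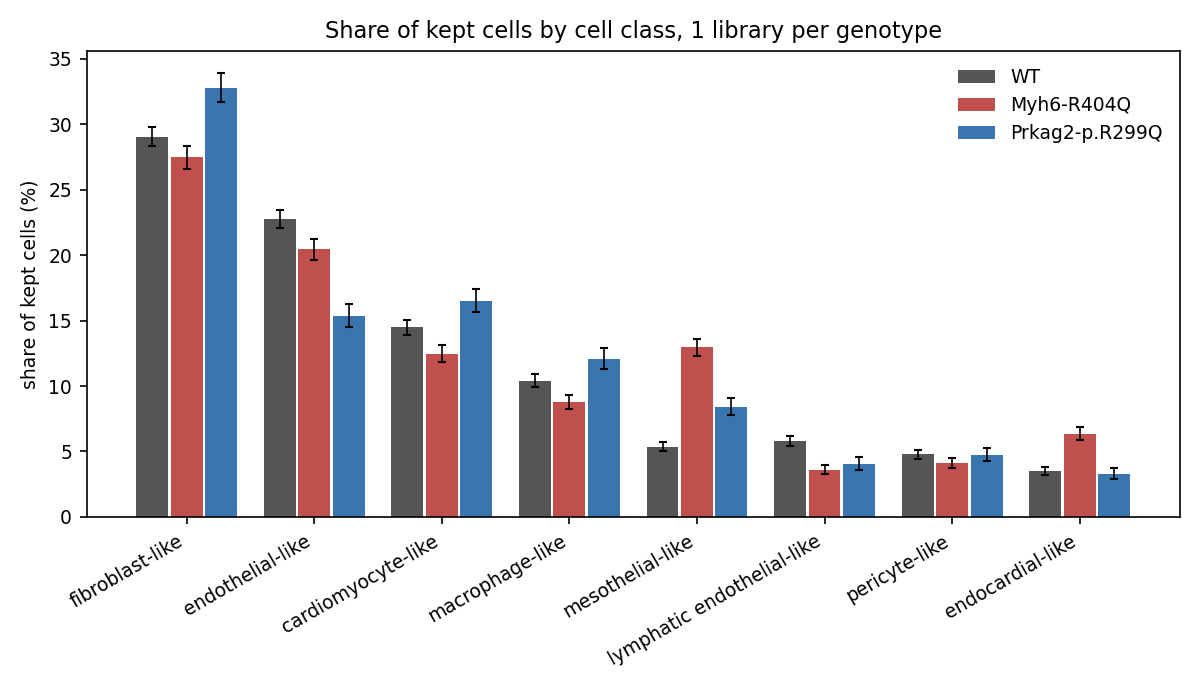
Share of kept cells (%) in the 8 classes with at least 200 cells in each library, 1 bar per library, with exact 95% binomial intervals as error bars. Mesothelial-like cells stand at 5.37% in WT, 12.96% in Myh6-R404Q and 8.43% in Prkag2-p.R299Q.

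Fibrosis is named in the study's title, so fibroblast-like cells were compared next. In Myh6-R404Q fibroblast-like cells the fibrillar and network collagens were higher than in WT as a group, with a median log2 ratio of 0.22 (0.16 to 0.27). This median lay at percentile 99.91 of random lists matched on expression. Of 15 measured collagen genes, 3 were at least 1.5 times higher and 0 at least 1.5 times lower. Col3a1, a fibrillar collagen of scars, was at 1163 CPM against 897 in WT, 1.30 times higher (1.25 to 1.34). Col1a1, the main fibrillar collagen, was 1.17 times (1.07 to 1.27) its WT level, Col15a1 1.53 times (1.46 to 1.61) and Col5a3 2.70 times (2.49 to 2.94). Col8a1 was 0.984 times its WT level (0.951 to 1.02). Matrix glycoproteins went both ways: of 30 measured, 4 were at least 1.5 times higher and 4 at least 1.5 times lower, with a median of -0.053 (-0.077 to 0.033). Elastin (Eln) was 2.08 times (1.94 to 2.23) and the basement membrane gene Nid1 1.52 times its WT level, while Tnc, a matrix protein of injured tissue, was 0.207 times (0.152 to 0.277).

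Genes of activated fibroblasts were not higher as a group in Myh6-R404Q. The myofibroblast list had a median of -0.061 (-0.19 to 0.069) over 15 measured genes, 2 at least 1.5 times higher and 3 at least 1.5 times lower. Fap, a surface protease of activated fibroblasts, was 1.79 times (1.66 to 1.93) its WT level. Postn, a matrix gene of activated fibroblasts, was at 33.7 CPM against 62.3, which is 0.542 times (0.456 to 0.642). Acta2 was at 6.47 CPM against 23.6, a gene of smooth muscle whose cells were also fewer in this library. The TGF-beta response list had a median of -0.044 (-0.10 to 0.035). Matrix proteases and their inhibitors had a median of -0.11 (-0.15 to 0.042), or 0.044 with cells thinned to 1000 UMIs, with Mmp3 at 0.319 times (0.244 to 0.412). Inflammatory mediators were lower as a group, with a median of -0.55 (-0.72 to -0.32), percentile 0 and 7 of 15 genes at least 1.5 times lower. Among them Ccl2, a chemokine that draws monocytes, was 0.317 times its WT level (0.239 to 0.416), Cxcl1 0.396 times (0.316 to 0.492) and the complement gene C4b 0.320 times (0.266 to 0.383). With members of at least 50 CPM alone the median was -0.17. In the same cells the heat shock list was at -0.62 and the immediate early list of tissue dissociation at -0.59.

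By size, the named genes with the highest ratios in Myh6-R404Q fibroblast-like cells included the clock transcription factors Npas2, 2.95 times (2.61 to 3.34), and Arntl, 2.38 times (2.05 to 2.77) the WT level. Others were Me3, a mitochondrial malic enzyme (2.95 times), Col4a6 (2.76), Slc7a11, the cystine transporter (2.73), and Rgs6 (2.55). The lowest were Serpina3n, a protease inhibitor of acute inflammation (0.183 times, 0.139 to 0.237), the metallothionein Mt2 (0.200), the complement gene C7 (0.214, 0.199 to 0.230), Prg4 (0.315) and the immediate early gene Egr1 (0.379).

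In Prkag2-p.R299Q fibroblast-like cells both collagens and matrix glycoproteins were higher than in WT as groups. The collagen median was 0.19 (0.12 to 0.28, percentile 99.88) and the glycoprotein median 0.17 (0.059 to 0.21, percentile 99.97). Free muscle RNA was lower in these cells than in WT, with a sarcomere list median of -0.94. CPM is a share of the class total, so less muscle RNA raises the share of other genes. How much this adds to the collagen and glycoprotein medians was not tested. Of 15 collagens 1 was at least 1.5 times higher and 0 at least 1.5 times lower. Of 29 glycoproteins 4 were at least 1.5 times higher and 1 was at least 1.5 times lower. Col1a1 was at 229 CPM against 157 in WT, 1.46 times higher (1.35 to 1.58), and Col3a1 was 1.43 times higher (1.39 to 1.48). Postn was at 107 CPM against 62.3, 1.72 times higher (1.52 to 1.95). Nid1 was 1.75 times (1.66 to 1.84) and the laminin chain Lamc1 1.22 times (1.19 to 1.26) the WT level, and Tnc 0.335 times (0.261 to 0.425). The myofibroblast list had a median of 0.10 (-0.068 to 0.19), the TGF-beta response list -0.063 (-0.16 to 0.012) and the protease list -0.055 (-0.097 to 0.072). Acta2 was at 15.9 CPM against 23.6, higher than in Myh6-R404Q although smooth muscle-like cells were fewer still in this library. Inflammatory mediators were lower, with a median of -0.25 (-0.40 to -0.12), and 4 of 16 genes were at least 1.5 times lower against 2 at least 1.5 times higher. C4b was 0.413 times (0.349 to 0.486) and Cxcl1 0.415 times its WT level. Here the heat shock list was at -0.45 and the immediate early list at -0.48. With cells thinned to 1000 UMIs the collagen median was 0.10, and with members of at least 50 CPM the inflammatory median was -0.12.

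Among the named genes of Prkag2-p.R299Q fibroblast-like cells, Islr was 2.79 times (2.27 to 3.45), Clvs1 2.41 times, Inmt 2.32 times and the potassium channel gene Kcnk2 2.20 times the WT level. Mt2 was 0.187 times (0.138 to 0.249), Egr1 0.308 times and Serpina3n 0.306 times. Hrc, Dsp, Pgam2 and Xirp2, all abundant in heart muscle, were also among the lowest, at 0.351, 0.380, 0.390 and 0.410 times. Free muscle RNA was present in these cells: Myh6 itself was at 2311 CPM in fibroblast-like cells of WT, 2078 of Myh6-R404Q and 1301 of Prkag2-p.R299Q. The fatty acid oxidation list, which muscle expresses strongly, had a median of -0.63 (-0.68 to -0.54) in Prkag2-p.R299Q fibroblast-like cells and -0.045 in Myh6-R404Q ones. The oxidative phosphorylation list had medians of -0.53 and -0.096.

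Set directly against each other, Prkag2-p.R299Q fibroblast-like cells had 4.51 times (4.19 to 4.85) the C7 and 3.18 times (2.70 to 3.75) the Postn of Myh6-R404Q ones. They had 0.157 times the Npas2 (0.130 to 0.187), 0.166 times the Arntl (0.130 to 0.208) and 0.424 times the Eln (0.392 to 0.457). The clock output genes Per3 and Dbp were 2.35 and 2.19 times higher.

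**Figure D2:**
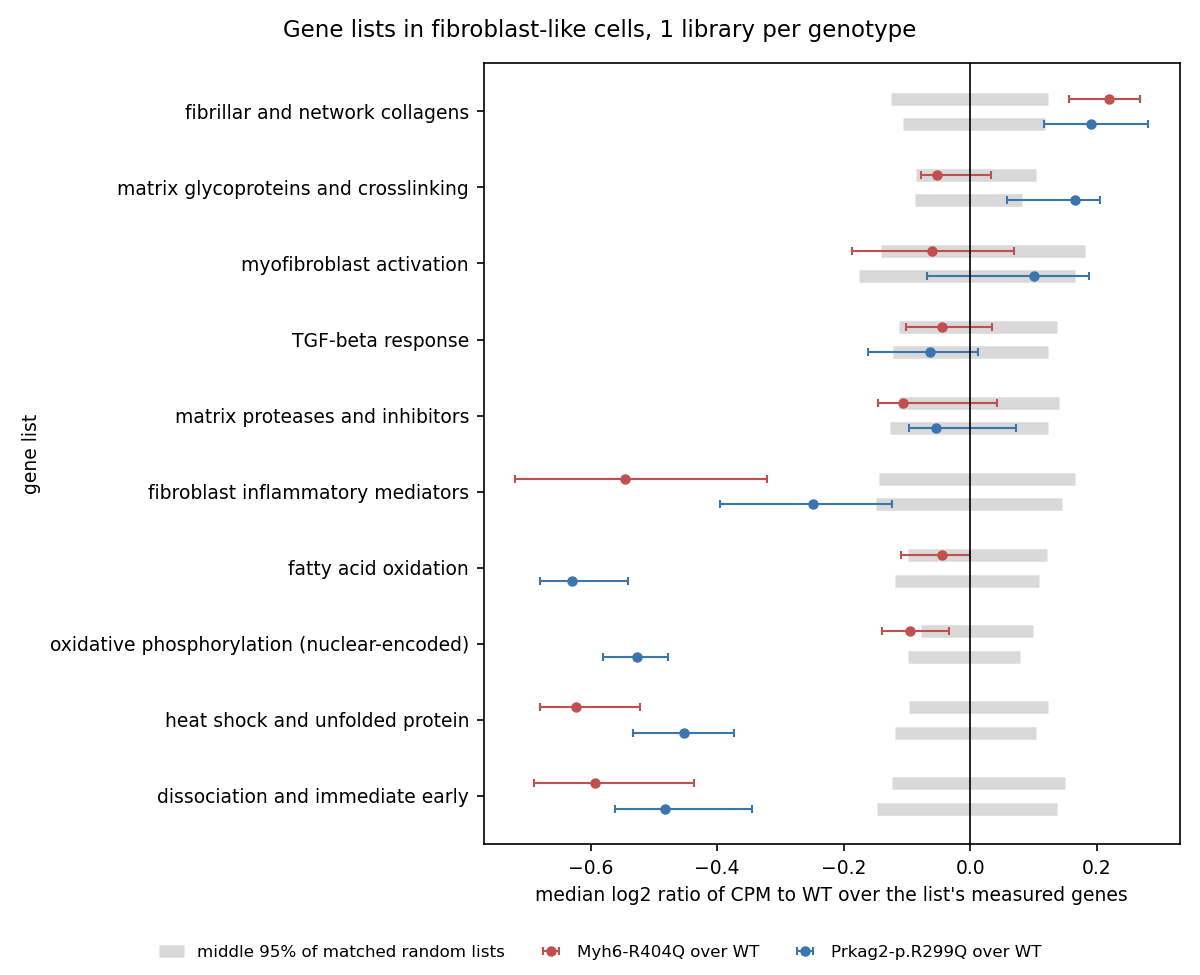
Median log2 ratio of CPM to WT over the measured genes of 10 lists in fibroblast-like cells, with 95% counting intervals, for Myh6-R404Q (red) and Prkag2-p.R299Q (blue), over grey bars that span the middle 95% of matched random lists. Collagens stand at 0.22 and 0.19, and inflammatory mediators at -0.55 and -0.25.

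Immune activation, also named in the title, was followed in macrophage-like cells. In Myh6-R404Q these cells had lower inflammatory cytokines and chemokines than WT as a group, with a median log2 ratio of -0.75 (-0.99 to -0.42) and percentile 0. Of 16 measured genes 9 were at least 1.5 times lower and 2 at least 1.5 times higher. The chemokine Ccl6 was at 82.8 CPM against 254 (0.326 times, 0.268 to 0.395), Ccl9 was 0.405 times (0.316 to 0.514) and Ccl2 0.461 times (0.286 to 0.722). The cytokine Il1b was at 13.7 CPM against 28.1 (0.487 times, 0.285 to 0.804), while Cxcl16 was 1.58 times higher (1.26 to 1.99). With every member that had a UMI the median was -0.17. In the same cells the heat shock list was at -0.54 and the immediate early list at -0.39. Antigen presentation genes of MHC class II were higher, with a median of 0.37 (0.28 to 0.66, percentile 99.53). Of 11 measured genes 4 were at least 1.5 times higher, among them H2-Ab1 (2.13 times, 1.65 to 2.76) and Cd74, at 219 CPM against 137. The makeup of the class differed too at the finer clustering. A cluster with Cd86, of this list, among its leading genes held 194 WT, 286 Myh6-R404Q and 197 Prkag2-p.R299Q cells. Another, with the resident markers F13a1, Vsig4, Cd163 and Cbr2, held 726, 458 and 525, and a further cluster 598, 167 and 94. Class medians may thus reflect makeup as well as differences within cells.

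Markers of resident macrophages had a median of -0.16 (-0.32 to 0.0099) in Myh6-R404Q, which was -0.33 with cells thinned to 1000 UMIs, where the MHC class II median was 0.67. Lyve1, a marker of vessel-associated resident macrophages, was at 103 CPM against 179 (0.574 times, 0.476 to 0.691), F13a1 was 0.589 times (0.570 to 0.607), and the transcription factor gene Maf 1.30 times. The lipid- and fibrosis-associated list was higher, with a median of 0.31 (0.080 to 0.49), 5 of 16 genes at least 1.5 times higher and 2 at least 1.5 times lower, but was at 0.021 with thinned cells and 0.064 with members of at least 50 CPM. Apoe, an apolipoprotein of macrophages, was 1.71 times (1.52 to 1.93) and Gpnmb 4.86 times (1.74 to 16.7) the WT level, and the lipase Lpl 0.631 times. Ccr2, the receptor of recruited monocytes, was at 35.5 CPM against 48.0 (0.740 times, 0.526 to 1.03), and the list of recruited macrophages had a median of 0.046 (-0.12 to 0.29). Spp1 had 2 UMIs in Myh6-R404Q, 6 in Prkag2-p.R299Q and 4 in WT, too few to compare. Named by size, Kctd16 (3.87 times), the transporter gene Slc7a15 (3.31), the fractalkine receptor Cx3cr1 (2.68, 2.03 to 3.56) and Hpgd (2.57) were highest. Clec4d, at 11.8 CPM against 69.7, the NAD-consuming enzyme Cd38 (0.202, 0.148 to 0.271), the chaperone Hsph1 (0.208) and Gda (0.257) were lowest.

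In Prkag2-p.R299Q macrophage-like cells the cytokine list was also lower than in WT, with a median of -0.35 (-0.60 to -0.077, percentile 0.29), 7 of 16 genes at least 1.5 times lower and 2 at least 1.5 times higher. Il1b was at 4.48 CPM, 0.159 times (0.0658 to 0.334) its WT level, and Ccl6 was 0.455 times (0.386 to 0.535). The cytokine median was -0.70 with members of at least 50 CPM, and in these cells the heat shock list was at -0.43 and the immediate early list at -0.28. Resident markers were higher, with a median of 0.23 (0.13 to 0.34, percentile 99.17), which was 0.075 with doublets removed at a fixed rate. Less free muscle RNA, with a sarcomere list median of -0.72, and the unlike makeup of the class given above may add to this median, untested. Lyve1 was at 259 CPM, 1.45 times higher (1.26 to 1.66), and Maf 1.33 times higher. Ccr2 was at 24.1 CPM, 0.502 times (0.343 to 0.723). MHC class II genes had a median of -0.14 (-0.33 to 0.096), with H2-Eb1 at 0.639 times (0.517 to 0.788). The lipid-associated list had a median of 0.14 (-0.049 to 0.29), with Apoe at 1.48 times and Lpl at 0.396 times (0.357 to 0.440), and the recruited list 0.26 (-0.14 to 0.47). Complement and phagocytosis genes had medians of 0.15 (-0.059 to 0.25) here and 0.066 (-0.11 to 0.15) in Myh6-R404Q. Named by size, the cell division gene Kif23 (2.94 times), Kctd16 (2.64) and the lysosomal enzyme gene Arsb (2.16) were highest. The mitochondrial genes Gpam (0.230) and Bnip3 (0.273) were lowest, along with the muscle enzyme Pgam2 (0.412) and Cd38 (0.423). Myh6 was at 2993, 2899 and 2198 CPM in macrophage-like cells of WT, Myh6-R404Q and Prkag2-p.R299Q. Between the mutants, Prkag2-p.R299Q had 2.52 times (2.11 to 3.03) the Lyve1, 0.417 times the H2-Aa and 0.428 times the Ciita, the master regulator of MHC class II.

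**Figure D3:**
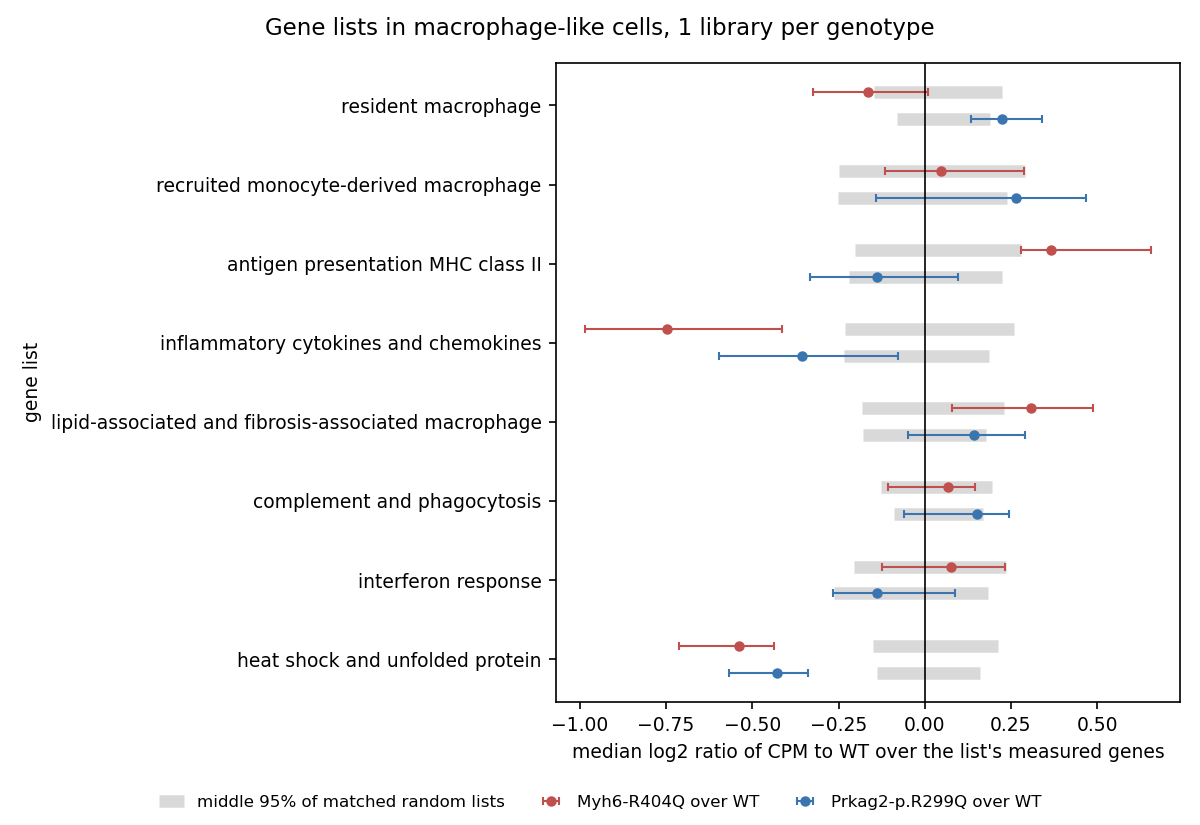
Median log2 ratio of CPM to WT over the measured genes of 8 lists in macrophage-like cells, with 95% counting intervals, for Myh6-R404Q (red) and Prkag2-p.R299Q (blue), over grey bars that span the middle 95% of matched random lists. Cytokines stand at -0.75 and -0.35 and MHC class II genes at 0.37 and -0.14.

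Cardiomyocyte-like cells had the highest level of Myh6 transcripts among the classes compared, though not of Prkag2 transcripts. In Myh6-R404Q, fatty acid oxidation genes were higher than in WT, with a median log2 ratio of 0.46 (0.43 to 0.57, percentile 100), 9 of 21 genes at least 1.5 times higher and 0 at least 1.5 times lower. Fabp3, the fatty acid carrier of heart muscle, was 1.63 times (1.56 to 1.70) its WT level, while the regulators Ppargc1a and Ppara were 0.816 and 0.861 times. Nuclear-encoded oxidative phosphorylation genes had a median of 0.36 (0.29 to 0.40), which was 0.19 without the Nppa cluster described below, with the ATP synthase subunits Atp5a1 and Atp5b at 1.39 and 1.48 times. Pdk4, a kinase that limits glucose oxidation, was at 103 CPM against 37.5 (2.74 times, 2.41 to 3.12). The fetal and hypertrophic program had a median of -0.0028 (-0.14 to 0.11). Its member Nppa, the atrial natriuretic peptide gene, was at 23.6 CPM against 23.1, a log2 ratio of 0.030 that was 1.15 with cells weighted equally, 1.84 thinned and -0.87 without the low-UMI cluster. Nppb, the B-type natriuretic peptide gene, was at 75.3 against 60.9 (1.24 times, 1.10 to 1.39). Myh7, the slow myosin of the fetal heart, was at 1319 against 1409 (0.936 times, 0.911 to 0.961). Myh6 was 0.965 times (0.957 to 0.973) its WT level, a direction that turned when cells were weighted equally or thinned to 1000 UMIs. The sarcomere list had a median of 0.029 (0.0098 to 0.050), which fell below 0 with TMM scaling, without the low-UMI or the Nppa cluster or with no doublets removed. Its member Myom2 was 3.00 times higher (2.82 to 3.20).

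Calcium handling genes in Myh6-R404Q had a median of -0.0026 (-0.085 to 0.022), with the ryanodine receptor Ryr2 at 0.608 times (0.602 to 0.614) and the exchanger Slc8a1 at 0.552 times. The glycogen and AMPK list had a median of 0.077 (-0.076 to 0.086), with the phosphorylase kinase subunit Phka1 at 0.474 times (0.443 to 0.507) and Ppp1r3a, which targets glycogen, at 0.578 times. Glycolysis genes had a median of 0.10 (0.041 to 0.21), or -0.0049 with TMM scaling and 0.027 without the Nppa cluster. By size, the highest named genes were Pak7 (7.67 times, 5.97 to 9.99), Scin (5.88), Rp1 (5.47), Erc2 (4.18) and Txnip, a glucose-responsive inhibitor of thioredoxin, at 323 CPM against 82.9 (3.90 times, 3.60 to 4.24). The lowest were Kctd8 (0.301), Kazn (0.333) and Ppm1e (0.443).

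In Prkag2-p.R299Q cardiomyocyte-like cells the natriuretic peptide gene Nppa was at 124 CPM (117 to 132) against 23.1 in WT, 5.36 times higher (4.63 to 6.24). The cells were not alike in this: a small cluster led by Nppa at the finer clustering, looked at after the values had been seen, held 10.6% of the class (8.81 to 12.5) in Prkag2-p.R299Q, 5.76% in Myh6-R404Q and 1.03% in WT. Since Nppa itself sets that cluster apart, values without it are lower by construction for Nppa and the genes that go with it. In Prkag2-p.R299Q its 118 cells held 507 Nppa UMIs at 2532 CPM, so they were shallow against the class median of 6607 UMIs. The low-UMI cluster, with a median of 962 UMIs, shared leading genes with it, among them Ankrd23, Xirp2, Ankrd1, Acta1 and Nppb. The overlap of their cells was not counted, so values without either cluster are not separate checks. The log2 ratio of Nppa, 2.37 in the whole class, was 3.62 with cells weighted equally, 3.76 with thinned cells and 1.64 without the low-UMI cluster. Outside the Nppa cluster the fold of Nppa was 3.05 (2.60 to 3.60). Nppb was 1.65 times higher (1.49 to 1.84), Myh7 1.29 times (1.26 to 1.32), Ankrd1, a stress-responsive muscle protein, 1.66 times (1.59 to 1.74), and Myh6 1.11 times (1.10 to 1.12). The fetal program had a median of 0.12 (0.036 to 0.19, percentile 98.56), with 4 of 15 genes at least 1.5 times higher and 2 at least 1.5 times lower, and -0.030 with every member that had a UMI. It was also -0.0031 without the Nppa cluster and 0.033 without the low-UMI cluster, against 0.25 with thinned cells, 0.22 with cells weighted equally and 0.21 with members of at least 50 CPM. The atrial light chain gene Myl7, looked at after Nppa had been seen, was at 1.14 CPM in this library, 2.43 in Myh6-R404Q and 1.62 in WT. Nppa was also 3.31 times higher (2.59 to 4.25) in endothelial-like cells, at 91.3 CPM. Myh6 was at 7438 CPM in those cells against 14259 in cardiomyocyte-like cells of this library, so free muscle RNA cannot be told apart there. The sarcomere list had a median of 0.13 (0.11 to 0.15), the fatty acid oxidation list 0.059 (-0.0019 to 0.083), the oxidative phosphorylation list 0.10 (0.041 to 0.14) and the calcium list -0.051 (-0.12 to -0.0035). The sarcomere median was 0.023 without the low-UMI cluster, 0.025 without the Nppa cluster, 0.051 with no doublets removed and 0.29 with cells weighted equally. The calcium list was above 0 with thinned or equally weighted cells, and at -0.16 and -0.15 without the low-UMI or the Nppa cluster. The other 2 lists went either way: fatty acid oxidation was at -0.063 without the low-UMI cluster, -0.095 without the Nppa cluster and -0.033 with doublets removed at a fixed rate, but at 0.38 with cells weighted equally, 0.28 thinned and 0.10 with TMM scaling. Oxidative phosphorylation was at -0.042 and -0.11 without those clusters, 0.0066 with no doublets removed, 0.46 with cells weighted equally and 0.44 thinned.

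The glycogen and AMPK list, which holds the pathway of the mutated kinase, had a median of -0.11 (-0.17 to -0.043, percentile 16.05) in Prkag2-p.R299Q cardiomyocyte-like cells. Of its 21 measured genes 0 were at least 1.5 times higher and 3 at least 1.5 times lower. The list was below 0 in all 8 classes of this library, 7 with their interval, and was lowest in lymphatic endothelial-like cells at -0.35 (-0.60 to -0.17). Outside muscle the foreign sarcomere list was below 0 in each class too, from -0.15 in endothelial-like cells to -0.88 in lymphatic endothelial-like and -0.94 in fibroblast-like cells. Less free muscle RNA may thus lower the list there, though Myh6 itself was 1.255 times its WT level in endothelial-like cells. Whether the lowering of the glycogen and AMPK list was particular to muscle therefore cannot be told. Ppp1r3a was 0.665 times (0.638 to 0.693) and Ugp2, which makes the glycogen precursor, 0.884 times the WT level. Glycolysis genes had a median of 0.0056 (-0.085 to 0.085), or 0.24 thinned and -0.16 without the Nppa cluster, with Pdk4 at 0.449 times (0.367 to 0.546). Other named genes were Lrp1b (2.53 times), Sorcs2 (2.20) and the stress kinase Map2k6 (2.20). Against Myh6-R404Q, Prkag2-p.R299Q cells had 5.25 times (4.47 to 6.19) the Nppa, 2.46 times the skeletal actin Acta1, 0.164 times (0.136 to 0.196) the Pdk4 and 0.276 times (0.254 to 0.299) the Txnip.

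**Figure D4:**
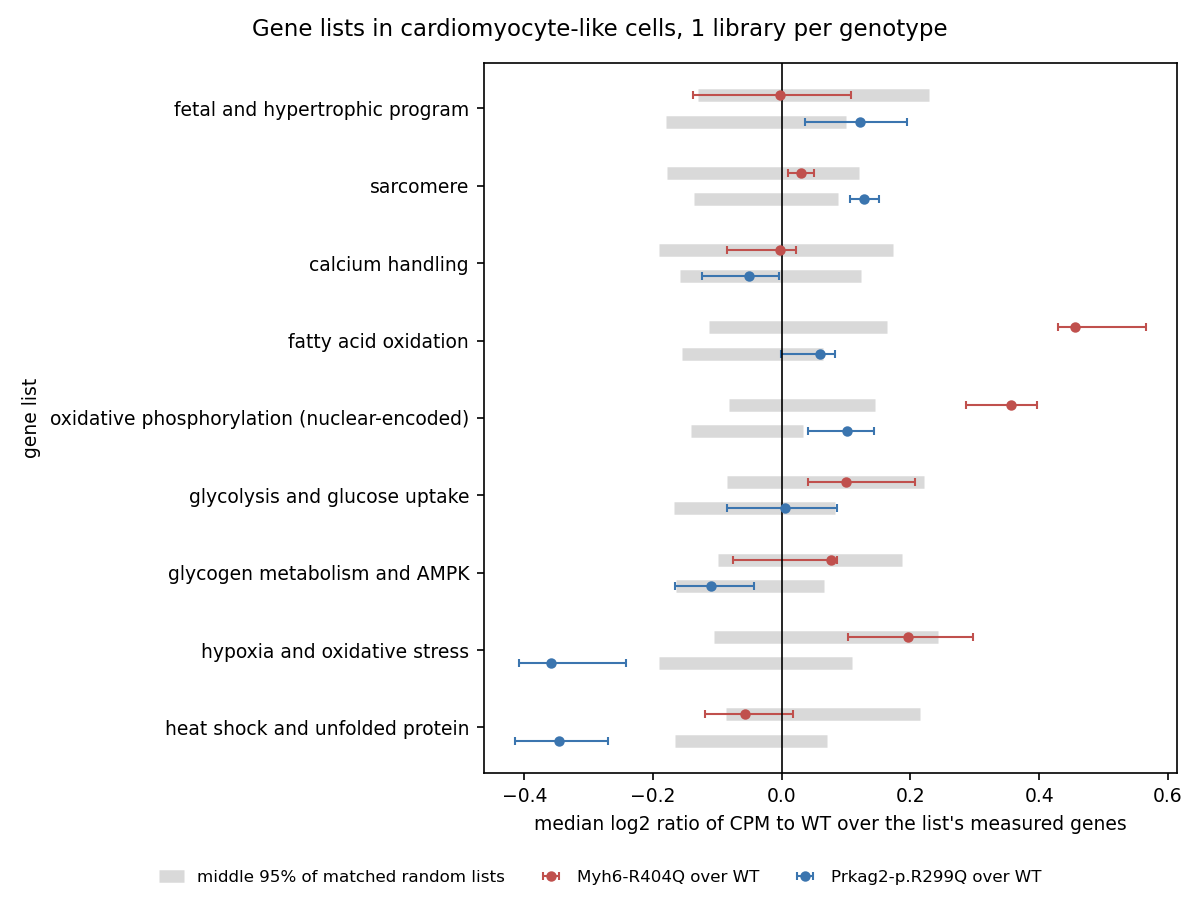
Median log2 ratio of CPM to WT over the measured genes of 9 lists in cardiomyocyte-like cells, with 95% counting intervals, for Myh6-R404Q (red) and Prkag2-p.R299Q (blue), over grey bars that span the middle 95% of matched random lists. Fatty acid oxidation stands at 0.46 and 0.059, and the fetal program at -0.0028 and 0.12.

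Endothelial-like cells had lower activation and adhesion genes in both mutants, with medians of -0.34 (-0.50 to -0.21, percentile 0.23) in Myh6-R404Q and -0.18 (-0.59 to -0.0015, percentile 7) in Prkag2-p.R299Q. In the same cells the heat shock list was at -0.32 and -0.33 and the immediate early list at -0.13 and -0.28, and arterial cells were 3.65% and 4.04% of the class against 6.57% in WT. Selp, the selectin that first holds leukocytes, was 0.249 times (0.126 to 0.455) and 0.233 times (0.0901 to 0.506) its WT level, and Lrg1 0.160 and 0.179 times. The angiogenesis list had medians of -0.018 (-0.12 to 0.072) and 0.0060 (-0.065 to 0.20). Its member Aplnr, the apelin receptor, was 2.15 times (1.75 to 2.64) and 2.14 times (1.70 to 2.70) higher, and Nrp2 1.49 and 1.58 times. Interferon response genes were higher, with medians of 0.25 (0.13 to 0.34) and 0.21 (0.048 to 0.29). Fatty acid handling had medians of -0.050 (-0.12 to -0.012) and -0.14 (-0.25 to -0.045), with Lpl at 0.857 and 0.732 times. The list of endothelial to mesenchymal transition had medians of -0.27 (-0.43 to -0.16) and -0.10 (-0.31 to 0.027), the latter 0.028 with thinned cells. Named in both mutants were the cell cycle inhibitor Cdkn1a (0.329 and 0.321 times) and Hsph1 (0.341 and 0.444). Myh6 in endothelial-like cells was at 5926 CPM in WT, 8076 in Myh6-R404Q and 7438 in Prkag2-p.R299Q, the highest level outside cardiomyocyte-like cells, so muscle RNA weighs on this class in particular.

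Mesothelial-like cells as a whole class showed higher interferon response and MHC class I genes in both mutants, and the makeup of the class differed as well. The interferon medians were 0.54 (0.37 to 0.68) in Myh6-R404Q and 0.51 (0.30 to 0.66) in Prkag2-p.R299Q, with 10 of 26 and 10 of 25 genes at least 1.5 times higher and 0 at least 1.5 times lower. The MHC class I medians were 0.45 (0.24 to 0.57) and 0.70 (0.50 to 0.83). A cluster with the mesothelial markers Msln, Krt19 and Upk3b, seen at the finer clustering and examined afterwards, held 27.5% of the class in Myh6-R404Q and 35.6% in Prkag2-p.R299Q against 10.2% in WT. Without it the interferon medians were 0.030 (-0.071 to 0.24) and 0.32 (0.094 to 0.48) and the MHC class I medians 0.21 (0.051 to 0.42) and 0.41 (0.16 to 0.55). Within it the interferon medians were 0.51 (0.33 to 0.87) and 0.38 (0.12 to 0.69), and those of MHC class I 0.063 (-0.080 to 0.48) and 0.17 (0.018 to 0.59). With members of at least 50 CPM the interferon median in Myh6-R404Q was 0.29. H2-K1, a classical MHC class I gene, was 1.49 times (1.35 to 1.65) and 1.76 times (1.57 to 1.96) its WT level. Among named genes, the Wnt enhancer Rspo2 was 10.7 times (5.72 to 22.5) and 11.2 times (5.88 to 23.8) higher, or 14.2 and 17.7 times without the Msln cluster. In Myh6-R404Q the lysophospholipase Enpp2 was 5.17 times and Brinp2 6.30 times higher, and Far2 0.213 times, or 7.51, 7.66 and 0.285 times without it. In Prkag2-p.R299Q the complement gene C3 was at 4169 CPM against 1189 (3.51 times, 3.33 to 3.69), Ifi27l2a 3.11 times and Fabp5 3.04 times higher, or 2.42, 2.16 and 2.15 times without the Msln cluster. A further mesothelial-like cluster, with a median of 636 UMIs, held 54 cells of Myh6-R404Q, 37 of Prkag2-p.R299Q and 13 of WT.

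In lymphatic endothelial-like cells Serpina3n was 0.0590 times (0.0189 to 0.141) in Myh6-R404Q and 0.151 times (0.0711 to 0.286) in Prkag2-p.R299Q, and Cmah, a sialic acid hydroxylase, 0.112 and 0.203 times its WT level. Bcl6b was 3.63 times higher in Myh6-R404Q and Prss23 2.83 times in Prkag2-p.R299Q. In endocardial-like cells Apoe was 3.02 times (2.47 to 3.72) and 2.95 times (2.35 to 3.72) higher. The notch target Hes1 was 2.79 times higher in Myh6-R404Q and the clock output gene Hlf 2.62 times in Prkag2-p.R299Q, where the inhibitory Smad6 was 0.375 times. In pericyte-like cells the fibronectin gene Fn1 was 2.14 times (1.61 to 2.85) higher in Myh6-R404Q, and Clstn2 2.18 times (1.81 to 2.63) in Prkag2-p.R299Q, where the matricellular gene Ccn2 was 0.367 times.

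Some lists moved the same way across the 8 classes compared. Heat shock genes had medians below 0 in all 8 classes of both mutants, from -0.62 in fibroblast-like cells to -0.056 in cardiomyocyte-like cells of Myh6-R404Q, and from -0.46 to -0.15 in Prkag2-p.R299Q. Hsp90aa1 in fibroblast-like cells of Myh6-R404Q was 0.486 times (0.431 to 0.546) and Hsph1 0.413 times its WT level. Immediate early genes linked to tissue dissociation did not share 1 direction: medians ran from -0.59 (-0.69 to -0.44) in fibroblast-like to 0.12 (-0.23 to 0.31) in endocardial-like cells of Myh6-R404Q, and from -0.48 (-0.56 to -0.34) in fibroblast-like to 0.25 (0.023 to 0.39) in mesothelial-like cells of Prkag2-p.R299Q, the last -0.13 without the Msln cluster. In fibroblast-like cells Junb was 0.421 and 0.410 times and Fos 0.454 and 0.253 times. Hemoglobin transcripts, which come from red blood cells, had medians between 1.84 and 2.14 in Myh6-R404Q and between 1.37 and 2.30 in Prkag2-p.R299Q. Mitochondrially encoded genes had medians between -0.48 and -0.11 and between -0.59 and -0.31. In Prkag2-p.R299Q the glycogen and AMPK list also lay below 0 throughout, from -0.35 to -0.11 in cardiomyocyte-like cells, the least lowered, while in Myh6-R404Q it ran from -0.22 to 0.077. Fatty acid oxidation genes of Prkag2-p.R299Q were below 0 in 7 of the 8 classes, down to -0.76 in lymphatic endothelial-like cells. Malat1, a nuclear retained RNA, was a higher share of UMIs than in WT in each class of Prkag2-p.R299Q. It was 5.39% against 4.13% in fibroblast-like cells and 8.31% against 5.95% in cardiomyocyte-like cells. In Myh6-R404Q it went either way. The nuclear retained RNA list had medians from -0.38 to 0.20 in Prkag2-p.R299Q. Median mitochondrial shares of cardiomyocyte-like cells were low, at 1.17% in WT, 1.03% in Myh6-R404Q and 0.83% in Prkag2-p.R299Q. Whether barcodes hold whole cells or mainly nuclear RNA was not tested, nor was a differing share of nuclear RNA between libraries.

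**Figure D5:**
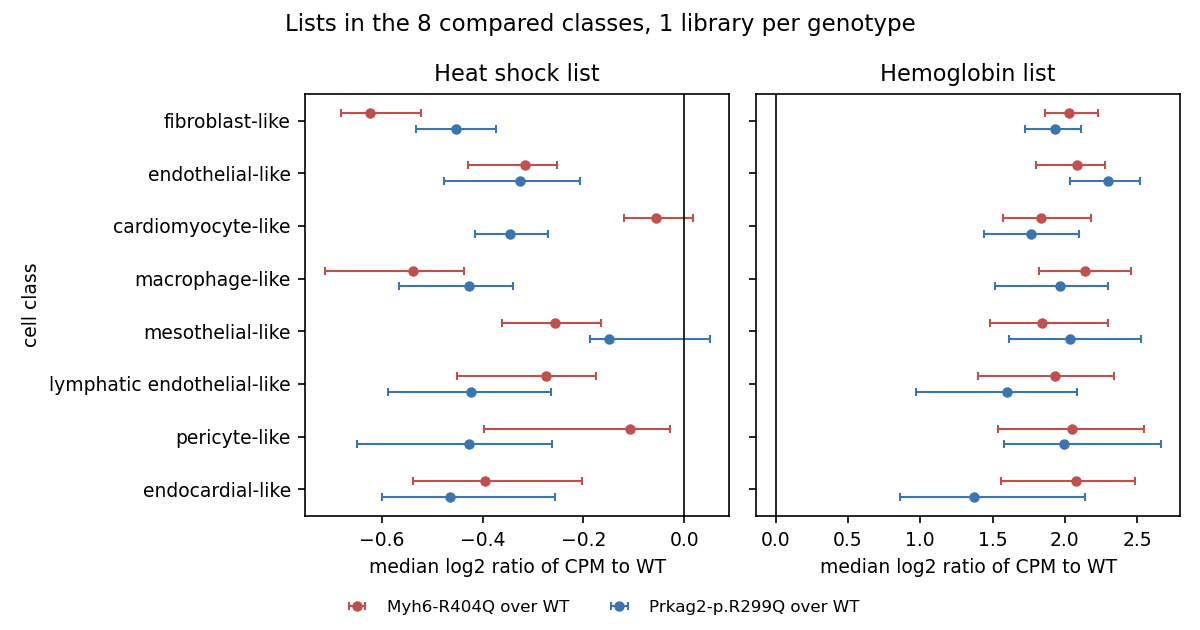
Median log2 ratio of CPM to WT of the heat shock list (left) and the hemoglobin list (right) in the 8 classes, with 95% counting intervals, for Myh6-R404Q (red) and Prkag2-p.R299Q (blue). Every heat shock median lies below 0, from -0.62 to -0.056, and every hemoglobin median above 0, from 1.37 to 2.30.

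The mutants were last compared in how their genes differed from WT. Across 4601 genes of fibroblast-like cells, the log2 ratios of the mutants to the shared WT library had a Pearson correlation of 0.624 and a covariance of 0.0592. The correlation was 0.637 in macrophage-like cells, 0.701 in endothelial-like cells and 0.572 in cardiomyocyte-like cells. Sampling of cells from a shared control gave positive but lower correlations. With 3 mock libraries drawn from WT cells, the means were 0.370, 0.355, 0.301 and 0.356 in the same order. The highest of the draws were 0.418, 0.422, 0.375 and 0.440. The covariances were 0.0592, 0.0908, 0.0606 and 0.0548, against mock covariances of 0.00363, 0.0118, 0.00621 and 0.00306. The WT library cannot be split into libraries, so the mock draws hold no difference between libraries. They matched numbers of cells but not UMIs, and WT cells were shallower, with a median of 1414 UMIs against 1849 and 2343 in the mutants. The mock mutants were thus noisier than the real ones, which may lower the mock correlations. Part or all of the excess may therefore come from the shared control. Genes are not independent replicates, and cardiomyocyte-like cells were added to this comparison after the data had been seen.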

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

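The clock tests of Myh6-R404Q below were set out after clock genes had been noticed in fibroblast-like and endocardial-like cells, though before the class values they use were seen, and the other tests were chosen after the results were seen.

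The mutants lay on opposite sides of WT in several results under the main settings, and these differences between the groups were not tested, since there is 1 library each. The ratio to WT in Prkag2-p.R299Q divided by that in Myh6-R404Q was 1.19 for the fibroblast-like share, 1.33 for the cardiomyocyte-like share and 1.38 for the macrophage-like share. With at least 1000 UMIs the cardiomyocyte-like share was below WT in both, at 13.03% and 16.84% against 17.36%, and with the Myh6-R404Q matrix as deposited the fibroblast-like share was above WT in both. For Postn in fibroblast-like cells it was 3.18, and for Lyve1 in macrophage-like cells 2.52. In cardiomyocyte-like cells it was 1.15 for Myh6 and 1.37 for Myh7, though Myh6 was above WT in both with thinned or equally weighted cells, at log2 ratios of 0.11 and 0.18 in Myh6-R404Q. The medians of the hypoxia and oxidative stress list in cardiomyocyte-like cells, 0.20 in Myh6-R404Q and -0.36 in Prkag2-p.R299Q, differed by -0.55. Those of the fatty acid oxidation list in endothelial-like cells, 0.15 and -0.17, differed by -0.32. The sarcomere list, foreign to these cells, lay on the same sides, at 0.078 and -0.15. Myh6 alone was higher than in WT in both, at 1.363 and 1.255 times, so in Prkag2-p.R299Q the measures of free muscle RNA went both ways. Free muscle RNA therefore cannot be told apart there. A cluster with cell cycle genes that was named for no class held 0.545% of Myh6-R404Q cells and 0.281% of Prkag2-p.R299Q cells against 0.0406% of WT cells, and no comparison used it. Its highest marker score was for macrophages, at 1.32 against 0.32 for the next class. The macrophage-like shares may thus leave out cycling macrophages.

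Heat shock genes were lower than in WT in both mutants, and fatty acid oxidation genes were lower in several classes of Prkag2-p.R299Q. Less free cardiomyocyte RNA is argued against as the whole cause for the heat shock list in 2 places, because the sarcomere list, foreign to these cells, had a median of only -0.21 in Myh6-R404Q fibroblast-like cells and -0.15 in Prkag2-p.R299Q endothelial-like cells, where the heat shock list had -0.62 and -0.33. It remains open in Prkag2-p.R299Q fibroblast-like cells, where the sarcomere median of -0.94 lay below the -0.45 of the heat shock list and the -0.63 of the fatty acid oxidation list, and for fatty acid oxidation in macrophage-like cells, with -0.72 below -0.55. A handling difference that touched the whole WT library also remains open. The heat shock median was below 0 in 16 of 16 pairs of class and mutant, but this restates the pattern and does not test it. The genotypes themselves remain open too, untested, because each has 1 library.

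Clock genes of opposite phase differed in Myh6-R404Q fibroblast-like cells, where the median of the Arntl arm minus that of the Dbp and Per arm was 0.56 (0.46 to 0.96). A different time of day at harvest of that library as the whole cause is argued against only weakly. The difference was above 0 in 4 of the 7 other classes, the highest count that the rule set beforehand took as evidence against. It was above 0 with its interval in 3, up to 1.06 (0.30 to 1.82) in mesothelial-like cells, and below 0 with its interval in 2. Of these, endocardial-like cells, where clock genes had already been noticed, had -1.13 (-1.53 to -0.55) from 2 measured genes of the Arntl arm. Harvest time is therefore not excluded. A clock difference arising in cardiomyocytes is argued against by their value of -0.42 (-0.65 to -0.19), below the median of 0.19 over the 7 other classes. In Prkag2-p.R299Q fibroblast-like cells the difference was -1.53 (-1.76 to -1.32), and a different time of day at harvest of this library remains open, since it was below 0 in 6 of the 7 other classes too, in 2 of them with its interval. Prkag2-p.R299Q set directly against Myh6-R404Q gave -2.33 in fibroblast-like cells. It gave -0.36 in endothelial-like, -0.56 in macrophage-like, -1.09 in mesothelial-like and -0.58 in pericyte-like cells, each with its interval below 0. Intervals included 0 in cardiomyocyte-like, lymphatic endothelial-like and endocardial-like cells, the last at 0.57. A different time of day between the mutant libraries thus remains open. The genotypes remain open, untested.

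Smooth muscle-like and Schwann-like shares were lower in both mutants. Doublet calling is argued against: with no doublets removed the smooth muscle ratio to WT was 0.345 (0.268 to 0.443) in Myh6-R404Q and 0.190 (0.128 to 0.284) in Prkag2-p.R299Q. Less large-vessel tissue in the mutant samples remains open, since arterial cells were also a lower share of endothelial-like cells, 0.555 times WT in Myh6-R404Q and 0.615 times in Prkag2-p.R299Q. The genotypes remain open as well, untested.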

How the results depend on the processing

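Using the Myh6-R404Q matrix as deposited and leaving out a cardiomyocyte-like or mesothelial-like cluster were chosen after the data had been seen, and the other alternatives before. Of 330 values of 39 share ratios under the alternatives, 14 had the opposite sign, as did 101 of 6096 values of 589 gene ratios and 159 of 2903 values of 197 list medians. In 3, 15 and 15 of these the interval of the reported value excluded 0, and the word turned below is kept for them. All values below are log2 ratios to WT unless said otherwise, and for each that turned or moved the cause was not tested, except that the deposited matrix mixes WT and Prkag2-p.R299Q cells in by its construction. No paired analysis was possible because each genotype has 1 library. Depth limits the rarer genes most, with median UMIs per kept cell of 1414 in WT, 1849 in Myh6-R404Q and 2343 in Prkag2-p.R299Q.

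Class shares depended on the UMI minimum and on doublet removal. With at least 1000 UMIs the endothelial-like share turned to 0.0083 in Myh6-R404Q and was -0.31 in Prkag2-p.R299Q, and the cardiomyocyte-like share turned to -0.043 in Prkag2-p.R299Q and was -0.41 in Myh6-R404Q. Under the same minimum mesothelial-like cells were at 1.15 in Myh6-R404Q and 0.34 in Prkag2-p.R299Q, where fibroblast-like cells were at 0.10 and macrophage-like cells at 0.34. With doublets removed at a fixed rate the fibroblast-like share was -0.14 in Myh6-R404Q and 0.098 in Prkag2-p.R299Q. The endothelial-like share was then -0.23 and -0.66, and the cardiomyocyte-like share -0.11 in Myh6-R404Q. With the matrix as deposited the fibroblast-like share in Myh6-R404Q turned to 0.013, while the cardiomyocyte-like share was -0.023, the macrophage-like share -0.024 and the mesothelial-like share 0.66.

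The deposited matrix also moved list medians of Myh6-R404Q. In fibroblast-like cells collagens were at 0.13, matrix glycoproteins at 0.055 and inflammatory mediators at -0.22, and the nuclear retained RNA list turned from -0.21 to 0.0052. In cardiomyocyte-like cells the fetal program was at 0.11, sarcomere genes at 0.061 and fatty acid oxidation at 0.17. In macrophage-like cells resident markers were at 0.079, MHC class II genes at 0.11 and cytokines at -0.29.

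Fibroblast-like and macrophage-like medians moved with the choice of members and with depth. Matrix glycoproteins in Myh6-R404Q were at -0.091 with TMM scaling and -0.085 with every member that had a UMI. Inflammatory mediators with members of at least 50 CPM were at -0.17 in Myh6-R404Q and -0.12 in Prkag2-p.R299Q. Cytokines in macrophage-like cells were at -0.17 in Myh6-R404Q with every member that had a UMI, and at -0.70 in Prkag2-p.R299Q with members of at least 50 CPM. With cells thinned to 1000 UMIs collagens in Prkag2-p.R299Q were at 0.10, fatty acid oxidation in Myh6-R404Q fibroblast-like cells turned from -0.045 to 0.019, resident markers in Myh6-R404Q were at -0.33 and MHC class II genes at 0.67. Resident markers in Prkag2-p.R299Q were at 0.075 with doublets removed at a fixed rate, where Fabp4 in Myh6-R404Q macrophage-like cells turned from -0.31 to 0.21. The ribosomal protein list in Prkag2-p.R299Q fibroblast-like cells turned from -0.044 to 0.0066 with at least 1000 UMIs.

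Cardiomyocyte-like values of Myh6-R404Q depended on several settings. The sarcomere median turned to -0.077 with TMM scaling, -0.048 without the low-UMI cluster, -0.041 without the Nppa cluster and -0.027 with no doublets removed. It was 0.00024 with doublets removed at a fixed rate, 0.14 with thinned cells and 0.15 with cells weighted equally. Fatty acid oxidation kept its direction, at 0.35 with TMM scaling, 0.34 without the low-UMI cluster, 0.36 without the Nppa cluster, 0.63 with thinned cells and 0.59 with cells weighted equally. Glycolysis turned to -0.0049 with TMM scaling. Atp2a2 turned from 0.026 to -0.080 with TMM scaling, -0.020 without the low-UMI cluster, -0.0096 without the Nppa cluster, -0.015 with doublets removed at a fixed rate and -0.030 with none removed. Tpm1 turned from 0.11 to -0.029 without the low-UMI cluster and -0.017 without the Nppa cluster. Myh6 turned from -0.051 to 0.11 with thinned cells and 0.18 with cells weighted equally, where Xirp2 turned from -0.34 to 0.066. TMM scaling shifted this class by -0.11 log2 units.

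In Prkag2-p.R299Q cardiomyocyte-like cells the fetal program turned to -0.030 with every member that had a UMI and to -0.0031 without the Nppa cluster. Nppa and other members of this list set that cluster apart, so its removal lowers them by construction. The low-UMI cluster shared leading genes with it, so leaving out either is not a separate check. The median was 0.033 without the low-UMI cluster, 0.25 with thinned cells, 0.21 with members of at least 50 CPM and 0.22 with cells weighted equally. Sarcomere genes were at 0.17 with TMM scaling, 0.023 without the low-UMI cluster, 0.025 without the Nppa cluster, 0.28 thinned, 0.29 with cells weighted equally, 0.16 with each library clustered on its own, 0.072 with doublets removed at a fixed rate and 0.051 with none removed. Fatty acid oxidation was at 0.10 with TMM scaling, -0.063 without the low-UMI cluster, -0.095 without the Nppa cluster, 0.28 thinned, -0.033 with doublets removed at a fixed rate and 0.38 with cells weighted equally. Without the low-UMI cluster oxidative phosphorylation turned to -0.042, and to -0.11 without the Nppa cluster. With thinned cells calcium handling turned to 0.040, Ttn from -0.13 to 0.10 and Mt2 from -1.14 to 0.098. With cells weighted equally calcium handling turned to 0.094 and Ttn to 0.19. In mesothelial-like cells without the Msln cluster Ifi27l2a turned from 0.55 to -0.072 in Myh6-R404Q and the immediate early list from 0.25 to -0.13 in Prkag2-p.R299Q.

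Between the mutants, genes of at least 10 CPM gave covariances of 0.0780 in fibroblast-like, 0.137 in macrophage-like, 0.0812 in endothelial-like and 0.0703 in cardiomyocyte-like cells. The correlations were then 0.595 in macrophage-like and 0.598 in endothelial-like cells. Over all barcodes Myh6 was at 6696 CPM in WT, 6330 in Myh6-R404Q and 7284 in Prkag2-p.R299Q.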

Other observations

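No test in this part was planned, and none of its values is offered with an explanation. Prkag2 was higher in macrophage-like than in cardiomyocyte-like cells of each library, at 356 CPM in WT, 278 in Myh6-R404Q and 375 in Prkag2-p.R299Q. In lymphatic endothelial-like cells Prkag2 was at 739, 746 and 861 CPM.

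Chaperone and clock genes aside, fibroblast-like cells also differed in immune genes. Interferon response genes, higher in mesothelial-like cells, were lower in fibroblast-like cells, with medians of -0.25 (-0.31 to -0.043) in Myh6-R404Q and -0.23 (-0.32 to -0.13) in Prkag2-p.R299Q. In macrophage-like cells they were at 0.075 (-0.12 to 0.23) and -0.14 (-0.27 to 0.089). MHC class I genes in Prkag2-p.R299Q had a median of -0.33 (-0.44 to -0.24) in fibroblast-like cells and -0.29 (-0.39 to -0.078) in macrophage-like cells.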
